A study of Mus musculus with 24 samples.

How the data were processed

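The series holds 24 microarrays of sorted mouse T cells in 8 groups of 3. Per the labels' protocols, Tregs of retired breeders were sorted as CD3+CD4+CD25+ cells, Tregs of the Pparg lines as CD25+YFP+ cells and Tconvs as CD3+CD4+CD25- cells, after exclusion of cells with CD11b, CD11c, B220, CD19 or CD8. The labels' protocols also name a double sort on a MoFlo, RNA extraction with TriZol and an Affymetrix whole transcript labelling kit. Per the submitters' processing notes, the authors computed the intensities with Affymetrix Power Tools and RMA, with no version given. The series' design text names RMA in GenePattern. The deposited values are RMA intensities on a linear scale, and log2 of the deposited intensity was computed here. They ran from 4.6085 to 28304.0 with 0 missing values, and no array was left out. The table gives no detection call, so no group mean is taken here to be above background where it lies under 83.8, the lowest median of an array, and folds over such a group are given as lower bounds with each of its arrays under that level set to it.

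Of the 25194 probe sets in the table, 21181 carry 1 gene symbol, 1379 several and 2634 none. The probe annotation that came with the series was used, and 21097 of the probe sets carry a gene identifier that the reference table of mouse genes knows, with 0 symbols updated through it. Tests used the probe sets with 1 symbol, and for the 909 genes with more than 1 such probe set the brightest by mean log2 intensity over all arrays, which left 19537 genes. The 4013 probe sets with several symbols or none were tested apart in the same model and are given as counts only. No genome build is named in the labels, so no coordinates are given; the order of genes in the reference table served only to find the neighbours of Foxp3.

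limma 3.58.1 in R 4.3.3 fitted all 24 arrays in 1 model with a mean per group and 16 residual degrees of freedom, followed by eBayes. Contrasts were VAT against LN Tregs, VAT Tregs against VAT Tconvs, LN Tregs against LN Tconvs, VAT against LN Tconvs and their interaction in retired breeders. In the Pparg lines they were mut against wt in VAT Tregs, titled mut against titled wt in LN Tregs, their interaction, and VAT against LN Tregs in wt and in mut. Tests were moderated t tests, two-sided, with Benjamini-Hochberg adjustment over the 19537 genes of 1 comparison, and a call was an adjusted p under 0.05. Errors given with log2 differences are standard errors of the model, those given with intensities are standard deviations of the 3 arrays, and folds are powers of 2 of the log2 differences, that is, ratios of geometric means, unless given as at least a size. The VAT Treg signature held the genes with a call and a log2 difference of at least 1 (2-fold) between VAT and LN Tregs of retired breeders.

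The 26 lists of genes, 16 of them programs and 10 kinds of cells, are: Treg identity, VAT Treg markers, lipid uptake and storage, fatty acid oxidation, sterol synthesis, glycolysis, cytokines, chemokine receptors and adhesion, naive and lymphoid-homing, lineage transcription factors, cell cycle, immediate early and dissociation stress, interferon-stimulated, NF-kB response, inhibitory and costimulatory receptors, T cell identity, macrophage and monocyte, dendritic cell, B cell, CD8 and NK cell, innate lymphoid type 2 and mast cell, adipocyte, fibroblast and mesothelial, endothelial and erythroid genes, and T cell receptor variable segments. They were written from general knowledge of the field, and the VAT Treg markers partly come from this study. Each was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 26 lists of a comparison; camera with an estimated correlation and fry were run beside it. Members are counted as called over all genes and, where the count differs, adjusted over the list alone. Older names were matched to current ones (for example Folr4 to Izumo1r and Emr1 to Adgre1). Members without a probe set of 1 symbol were left out, among them Il1rl1, Areg, Sell, Tcf7, Gapdh, Stat1 and Isg15; the erythroid list kept 4 of its 12 names.

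Groups, comparisons, lists, the rule for named genes and the other settings listed below were fixed before the data were examined, with 3 exceptions. Added after seeing the data were the omission of replicate 3 of all 4 groups of retired breeders and the signature without the stress list or without genes called in VAT against LN Tconvs. Genes named are, per comparison, the 8 largest increases and the 8 largest decreases among calls whose replicates do not overlap (5 each way for both interactions and the tissue comparisons of the Pparg lines), leaving out unnamed or predicted genes, olfactory and vomeronasal receptors and receptor segments. Pparg, Foxp3, Il2ra, Klrg1, Gata3, Il10, Ccr2 and Cd36 and up to 4 members per list with the smallest adjusted p could also be named, and Il1rl1 was on this rule but has no probe set of its own here. Any other gene named is said to have been chosen after its values were seen.

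The same replicate number in different groups was not taken as a pair, since the labels do not say that it marks a shared pool or day. Alternatives tried were a replicate block, only the compared groups in the fit, an intensity trend with a robust prior, weights per array, quantile normalization of the columns, columns shifted to the same median, an offset of 50 before log2, the mean of a gene's probe sets, omission of the dimmest 40% of genes, all probe sets, a 2-fold limit with and without the test, omission of each array in turn and the signature by adjusted p alone. For the LN samples of the Pparg lines, the genotype field in place of the title and the other LN group were tried too. Every split of the 6 arrays of a comparison into 3 and 3 was also run. The model was tested on simulated data with the spread of these arrays and 19537 genes: of genes set to differ by a log2 of 0.5, 1 and 2 between VAT mut and wt Tregs, 43.3%, 95.5% and 100.0% were called, with 7 false calls, and for an interaction 22.4%, 83.6% and 100.0%, with 2 false calls. The simulated errors were independent for each gene and array, so these counts do not cover structure that genes or arrays share. Other tools were python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.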

Results

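Gene expression was measured with microarrays in CD4 T cells sorted from visceral adipose tissue (VAT) and lymph nodes (LN) of male C57BL/6 mice of 30 weeks. The sorted cells were regulatory T cells (Tregs, CD4 T cells that restrain immune responses) and conventional CD4 T cells (Tconvs). The 24 arrays fell into 8 groups of 3. In retired breeders, Tregs (CD25+) and Tconvs (CD25-) were taken from both tissues, giving 4 groups. In mice of the Pparg lines, Tregs were sorted as CD25+YFP+ cells from both tissues of mice titled wild type (wt) or mutant (mut) for Pparg, giving the other 4. Per the series' design text, the cells of several mice were pooled for each sample, so the p-values below measure the spread between pools. The labels do not say whether the mice differed from pool to pool. Each array correlated with the other arrays of its group at a mean Pearson's r of 0.9877 to 0.9956 across genes. The number of arrays, 3 per group, limited the precision, and the median standard error of a log2 difference between 2 groups was 0.129. The table holds no detection calls, so a group mean under 83.8, the lowest median of an array, is not shown here to be above background. Folds over such a dimmer group are given as at least the fold over 83.8 (its arrays under that level set to it, means of log2 values). Log2 differences are those of the measured signals, and the order of genes by size is not exact where a group is that dim. Interactions that involve such a group are differences of measured signals only.

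Pparg encodes a nuclear receptor for lipid ligands and is best known as the master regulator of fat cell differentiation. Its intensity was 728, 772 and 632 in the VAT Tregs of retired breeders and 83, 79 and 89 in VAT Tconvs. In LN it was 63, 56 and 54 in Tregs and 47, 72 and 61 in Tconvs. In the Pparg lines it was 457, 591 and 548 in wt VAT Tregs and 202, 198 and 199 in mut VAT Tregs. LN Tregs titled wt gave 57, 71 and 59, and those titled mut gave 71, 62 and 62. Pparg was thus 2.66-fold lower in mut than in wt VAT Tregs (log2 difference -1.41 ± 0.13 SE, n = 3 against 3, limma adjusted p = 1.65e-08), yet at least 2.38-fold higher in mut VAT Tregs than in LN Tregs titled mut (log2 1.62 ± 0.13, adjusted p = 1.49e-09). The labels do not say which part of the gene was removed, and the probe set may lie partly outside it, so the remaining signal does not measure how much of the gene was left. For the LN Tregs of the Pparg lines, titles and genotype fields contradict each other: samples titled wt carry the genotype Pparg- and those titled mut carry Pparg+. Pparg itself differed by less than its error there (log2 0.06 ± 0.13, adjusted p = 1), so it did not settle the labels. These groups are named by their titles, and signed LN values are given as titled mut minus titled wt. Of 31 genes called between them, 26 had the same sign in VAT by these titles, which argues against crossed titles. The genes are not independent of each other, so the direction is not taken as settled.

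**Figure D1:**
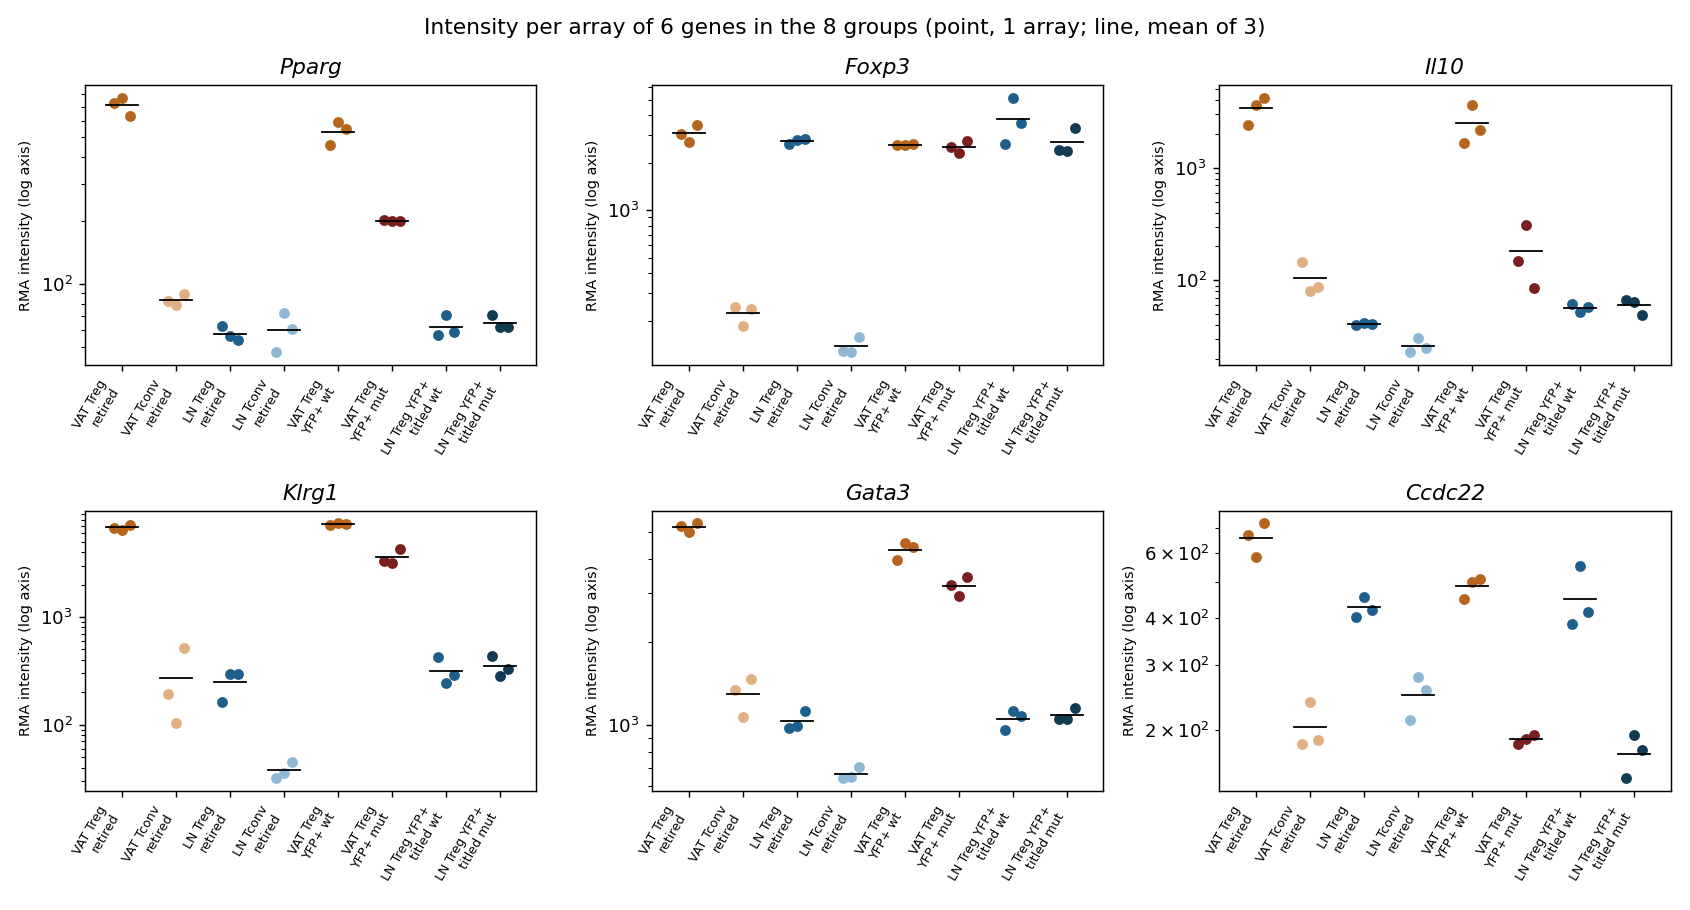
Intensity of 6 genes (Pparg, Foxp3, Il10, Klrg1, Gata3 and Ccdc22) on a log axis, with 1 point per array and 8 groups of 3 arrays along the horizontal axis. Pparg was at 632 to 772 in the 3 VAT Treg arrays of retired breeders and at 198 to 202 in the 3 mut VAT Treg arrays, while Foxp3 overlapped between mut and wt VAT Tregs.

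To ask how Tregs of fat differ from those of lymph nodes, VAT and LN Tregs of retired breeders were compared. VAT Tregs held at least 39.5-fold more mRNA signal for Il10, an anti-inflammatory cytokine (intensity 3394 ± 901 against 41.2 ± 0.6, mean ± SD, n = 3 each; log2 6.33 ± 0.31 SE). The chemokine gene Cxcl2 was at least 20.3-fold and the chemokine receptor gene Ccr1 at least 8.40-fold higher. Klrg1, an inhibitory receptor of differentiated lymphocytes, stood at 6776 ± 335 against 251 ± 77.0 (28.0-fold). Gata3, a transcription factor of type 2 immunity, rose 5.05-fold, Ccr2 rose 23.0-fold, and Pparg rose at least 8.46-fold to 711 ± 71.7 from 57.5 ± 4.9 (log2 3.63 ± 0.13, adjusted p = 1.82e-17). Other large increases were in Anxa1, Lilr4b, Pcsk1, Fosb and Kcna4, with log2 differences of 4.93 to 5.86. Foxp3, the factor that defines Tregs, was not called (log2 0.15 ± 0.17, adjusted p = 0.659), nor was the interleukin 2 receptor gene Il2ra (0.26 ± 0.18, adjusted p = 0.389). The largest decreases were in Igfbp4 (63.5 ± 10.9 against 885 ± 84.5, log2 -3.81 ± 0.21), the RNA sensor gene Tlr7 (-3.69), the protease gene Ctsw (-3.67), Nsg2 (-3.59), Iigp1 (-3.47), Rtp4 (-3.43), Ms4a4b (-3.40) and Cd96 (-3.37). In all, limma called 4263 of 19537 genes, 2079 higher and 2184 lower in VAT, and 990 of them differed by at least 2-fold (663 higher, 327 lower). With weights per array the call count was 7963.

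By the gene lists, 18 of 19 measured VAT Treg markers rose and 0 fell (median log2 2.74, camera adjusted p = 7.47e-34). That list was drawn partly from this study, so its direction is not independent evidence here or later. Of 24 immediate early and dissociation stress genes, which cells switch on within minutes of stimulation or handling, 22 rose (median 2.62, adjusted p = 7.47e-34), among them Fos (21.2-fold), Atf3 (at least 16.5-fold) and Junb (6.65-fold), and only Egr2 fell. Of 16 naive and lymphoid-homing genes 14 fell (median -1.82, adjusted p = 1.26e-17), such as Bach2 (-3.28), Satb1 (-3.22) and Actn1 (-3.19), and only Il7r rose. These 3 calls held with an estimated correlation between genes (adjusted p = 0.00281, 0.00134 and 0.0333). Members that are named as exceptions to a list's direction, here and later, were chosen after their values were seen. Counts adjusted over the list alone were the same for these lists. The next calls did not hold with an estimated correlation. Interferon-stimulated genes fell in 17 of 20 cases (median -1.03, adjusted p = 4.89e-12, and adjusted p = 0.0815 with an estimated correlation), for example Usp18 (-2.87) and Irf9 (-1.25), while Mx1 rose. Sterol synthesis genes rose in 12 of 15 cases (median 0.82, adjusted p = 6.21e-10, and adjusted p = 0.0815 with an estimated correlation), among them Idi1 (1.47), Hmgcs1 (1.43) and Sqle (1.28). Of 24 chemokine receptor and adhesion genes 15 rose, such as Cxcr6 (20.6-fold) and Ccr3 (at least 11.2-fold), and 6 fell, such as Itgae (-2.80) (adjusted p = 5.24e-07, and adjusted p = 0.0861 with an estimated correlation).

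Of 19 cytokine genes 8 rose (9 adjusted over the list alone), including Csf1 (2.04) and Il5 (1.73), and Lta fell (-1.89); the list gave adjusted p = 0.000846, and adjusted p = 0.0854 with an estimated correlation. Lineage transcription factors rose in 9 of 18 cases (10 adjusted over the list alone) and fell in 1, Stat5a, with Rora at 3.04 and Prdm1 at 2.40 (adjusted p = 4.66e-05, and adjusted p = 0.285 with an estimated correlation). Of 24 Treg identity genes 6 rose (8 adjusted over the list alone) and 10 fell, the latter with Lrrc32 (-3.07), Gpr83 (-2.90) and Itgae (median of the list -0.02, adjusted p = 0.047, and adjusted p = 0.659 with an estimated correlation). Fatty acid oxidation genes rose in 7 of 19 cases (8 adjusted over the list alone) with 1 decrease, Ppargc1b, and Cpt1a, the gatekeeper of mitochondrial fatty acid import, rose 3.02-fold; the list gave adjusted p = 0.0256, and adjusted p = 0.603 with an estimated correlation. Glycolysis genes rose in 4 of 15 cases and fell in 1, Hk2 (adjusted p = 0.0263, and adjusted p = 0.603 with an estimated correlation). Lipid uptake and storage genes went both ways, 8 of 29 up and 6 down (adjusted p = 0.279). Plin2, which coats lipid droplets, rose 15.1-fold there and Dgat1, a triglyceride synthase gene, rose 6.98-fold, whereas Scd2 fell (-1.76). Of 13 NF-kB response genes 5 rose and 2 fell (adjusted p = 0.266), with Tnfaip3, an inhibitor of the pathway, up 10.3-fold. Inhibitory and costimulatory receptor genes gave 6 of 17 up and 3 down (adjusted p = 0.216), Btla among the latter (-2.93). None of 29 cell cycle genes passed in limma, and the list gave a median of 0.06 (camera adjusted p = 0.826).

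In fat, the Treg to Tconv comparison asks what sets Tregs apart from their neighbours in the same tissue. Il2ra was 33.0-fold (3502 ± 839 against 107 ± 30.2) and Foxp3 13.8-fold (3062 ± 388 against 222 ± 31.8) higher in VAT Tregs, n = 3 each. Pparg was at least 8.30-fold higher (log2 3.09 ± 0.13, adjusted p = 5.09e-16), Il10 32.6-fold, Klrg1 31.0-fold, Gata3 4.07-fold and Ccr2 7.43-fold. Cxcl2 (5.80), Pcsk1 (5.22), Ccr1 (5.17), Frmd5 (5.11) and Kcna4 (4.56) completed the top increases on the log2 scale. Tconvs held more of the chemokine gene Ccl5 (3724 ± 1608 against 183 ± 27.7, log2 -4.25 ± 0.24) and of Ifng, the cytokine of type 1 T cells (-3.85 ± 0.31). They also held more of Dapl1 (-4.02), Igfbp4 (-3.93), Themis (-3.86), Gramd3 (-3.86), Mctp2 (-3.79) and Ehd3 (-3.72). limma called 3376 genes, 1911 higher and 1465 lower in Tregs, and 823 of at least 2-fold. The share of calls that were higher was 56.6%, and 71.0% when the columns were shifted to the same median.

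Treg identity genes rose in 13 of 24 cases (15 adjusted over the list alone) and fell in 2, Nt5e and Izumo1r (median 0.83, camera adjusted p = 2.09e-12). VAT Treg markers rose in 18 of 19 (median 2.02), immediate early and stress genes in 21 of 24 (median 1.34), and naive and lymphoid-homing genes fell in 13 of 16 (15 adjusted over the list alone, median -2.11), for instance Lef1 (-2.27). CD8 and NK cell genes, which stand for cytotoxic lymphocytes, were lower in 7 of 15 cases (median -0.44), such as Gzmk (-2.47) and Klrd1 (-1.58), and Itga2 was higher. Innate lymphoid type 2 and mast cell genes were higher in 5 of 13 cases (6 adjusted over the list alone; median 0.06), such as Kit (2.05). These 6 calls held with an estimated correlation (adjusted p = 0.032, 0.00288, 0.00288, 0.0165, 0.0019 and 0.0262 in this order). Interferon-stimulated genes fell in 13 of 20 cases and NF-kB genes rose in 8 of 13 (9 adjusted over the list alone), with adjusted p = 0.295 and adjusted p = 0.184 with an estimated correlation. T cell identity genes were lower in 7 of 13 cases (9 adjusted over the list alone), with Trat1 at -2.80, Cd28 at -0.77 and Cd3d at -0.61 (adjusted p = 4.26e-05, and adjusted p = 0.125 with an estimated correlation). Sterol synthesis genes rose in 8 of 15 (11 adjusted over the list alone; adjusted p = 1.07e-06, and adjusted p = 0.125 with an estimated correlation). The other lists called with the preset correlation alone were chemokine receptors and adhesion, lipid uptake and storage, fatty acid oxidation, inhibitory and costimulatory receptors, glycolysis and lineage transcription factors (in this order adjusted p = 0.111, 0.125, 0.295, 0.473, 0.481 and 0.498 with an estimated correlation).

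The same cell type comparison in lymph nodes gave fewer calls, 1786 genes (1026 higher and 760 lower in Tregs, 334 of at least 2-fold). Il2ra rose at least 34.3-fold (2872 ± 37.4 against 44.1 ± 7.0, n = 3 each) and Foxp3 20.1-fold (2754 ± 102 against 138 ± 17.9). Lrrc32, an anchor for latent TGF-beta, rose at least 21.6-fold, the inhibitory receptor gene Ctla4 16.4-fold, Ikzf2 16.2-fold and Nrp1 at least 11.7-fold. Rgs1 (4.60) and Socs2 (4.39) also led, the latter with a second probe set at 1.20. Decreases were largest in Pde3b (1111 ± 200 in Tconvs against 56.1 ± 25.9, log2 -4.38 ± 0.24), Atp8b4 (-3.69), Vipr1 (-3.01, other probe set -1.65), Dapl1 (140 against 1101 in Tconvs), Lypd6b (-2.79), Mctp2 (-2.78), Il1rl2 (-2.77) and Ggt5 (-2.28). Pparg did not pass (log2 -0.04 ± 0.13, adjusted p = 0.864), nor did Il10 (0.65 ± 0.31, adjusted p = 0.179), while Klrg1 (2.69) and Ccr2 (1.52) rose. Pparg (57.5 against 59.8) and Il10 (41.2 against 26.5) lay under 83.8 in both groups, so their missing calls do not show that they were unchanged. All 24 measured Treg identity genes rose (median 2.76, camera adjusted p = 9.89e-80, and adjusted p = 1.31e-05 with an estimated correlation). Inhibitory and costimulatory receptor genes rose in 10 of 17 (11 adjusted over the list alone) and Cd40lg fell (median 1.16, adjusted p = 7.96e-15, and adjusted p = 0.0314 with an estimated correlation). Cell cycle genes rose in 7 of 29 cases (11 adjusted over the list alone; median 0.55, adjusted p = 2.07e-08, and adjusted p = 0.376 with an estimated correlation), with Mcm6 at 0.87 ± 0.16. This count rested on single arrays: it was 4178 without LN Treg array 1, 1174 without LN Treg array 2, 983 without LN Treg array 3 and 1088 without LN Tconv array 2. It was 8364 with weights per array and 1146 with only these 6 arrays in the fit. The share of calls that were higher in Tregs, 57.4%, was 70.7% with columns shifted to the same median and 36.5% with weights per array, so which direction held more calls rested on the setting.

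Conventional T cells also differed between the tissues. VAT Tconvs were higher in Ifng (at least 11.1-fold, 1007 ± 465 against 72.6 ± 8.6, n = 3 each, log2 3.69 ± 0.31), Ccl5 (13.9-fold), the cytotoxic granule gene Nkg7 (15.1-fold), Cxcr3, a chemokine receptor of type 1 T cells (11.5-fold), S100a6 (at least 9.62-fold), Anxa1 (at least 3.90-fold), Lilr4b (at least 6.51-fold) and Socs2 (at least 9.60-fold, log2 4.43, with 1.15 at its other probe set). Decreases were smaller, led by Ifit1 (-1.73), Treml2 (-1.65), H2-T24 (-1.60), Igfbp4 (-1.56), Amigo2 (-1.48), Rtp4 (-1.48), Usp18 (-1.47) and Slc16a5 (-1.43). Klrg1 (2.54), Gata3 (0.95), Il10 (1.95) and Ccr2 (3.15) rose here too. So did Il2ra, which encodes the CD25 that the Tconv sort selected against (107 ± 30.2 against 44.1 ± 7.0, log2 1.25 ± 0.18, adjusted p = 1.98e-05). Foxp3 (222 ± 31.8 against 138 ± 17.9, log2 0.69 ± 0.17) and Pparg (0.50 ± 0.13) passed with adjusted p = 0.0092 and 0.0156, and each call was lost under 5 of the alternatives. Pparg lay under 83.8 in both groups (83.4 ± 5.0 against 59.8 ± 12.4), so it is not shown to be above background in either. limma called 1489 genes, 897 higher and 592 lower in VAT, 314 of at least 2-fold. The count was 828 without VAT Tconv array 3, 2795 with weights per array and 948 with only these 6 arrays in the fit.

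Among the lists, immediate early and stress genes rose in 19 of 24 cases in VAT Tconvs (20 adjusted over the list alone; median 1.39, camera adjusted p = 4.13e-37), VAT Treg markers in 16 of 19 (median 1.30) and Treg identity genes in 15 of 24 (18 adjusted over the list alone; median 1.02). Chemokine receptor and adhesion genes rose in 14 of 24 (15 higher and 2 lower adjusted over the list alone; median 1.09). Lineage transcription factors rose in 12 of 18 (13 adjusted over the list alone) with Bhlhe40 at 3.32 and Tbx21, the type 1 master regulator, at 2.95. Cytokine genes rose in 7 of 19 (8 adjusted over the list alone). Inhibitory and costimulatory receptor genes rose in 11 of 17, Ctla4 at 2.86 and Pdcd1 at 1.96. CD8 and NK cell genes rose in 6 of 15 (6 higher and 1 lower adjusted over the list alone), with Gzmk at 2.16 and Eomes at 1.95. These 8 list calls held with an estimated correlation (highest adjusted p = 0.00761). Cell cycle genes rose in 12 of 29 (19 adjusted over the list alone; median 0.75) and interferon-stimulated genes fell in 12 of 20 (14 adjusted over the list alone; median -0.55), with adjusted p = 0.193 and adjusted p = 0.0668 with an estimated correlation.

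Whether fat set Tregs apart from nodes in another way than it did Tconvs was tested as an interaction of tissue and cell type. The VAT to LN difference was larger in Tregs for Cxcl2 (log2 6.17 ± 0.30 SE), Pcsk1 (5.26), Ccr1 (5.17), Kcna4 (5.06) and Frmd5 (4.74), and for Il10 (4.38 ± 0.44), Pparg (3.13 ± 0.19, adjusted p = 2.67e-12), Klrg1 (2.27) and Gata3 (1.39). It was lower in Tregs for Cxcr3 (-4.34), Ctsw (-4.25), Cxcr5 (-4.21), Ifng (-4.17) and Slamf6 (-3.90). Treg identity genes were lower in 18 of 24 cases and higher in 1, Swap70 (21 lower adjusted over the list alone; median -1.75, camera adjusted p = 3.71e-32). Between VAT and LN Tregs this list had calls both ways, while most of its members rose in VAT against LN Tconvs. Its negative interaction thus does not show a general loss of these genes in VAT Tregs. VAT Treg markers were higher in 13 of 19 (14 adjusted over the list alone; median 1.37) and naive and lymphoid-homing genes lower in 13 of 16 (14 adjusted over the list alone; median -1.42). Immediate early and stress genes were higher in 15 of 24 with only Rgs1 lower (17 higher and 2 lower adjusted over the list alone; median 1.03), and CD8 and NK cell genes lower in 6 of 15. Innate lymphoid type 2 and mast cell genes were higher in 4 of 13 (5 adjusted over the list alone; median 0.28), with Kit at 1.59. These 6 lists held with an estimated correlation (adjusted p = 0.00285, 0.0173, 0.0173, 0.0201, 0.0173 and 0.0261). The inhibitory and costimulatory receptor, T cell identity, sterol synthesis, interferon-stimulated and cell cycle lists were called with the preset correlation alone (in this order adjusted p = 0.162, 0.162, 0.211, 0.409 and 0.494 with an estimated correlation). limma called 1503 genes, 819 higher and 684 lower, and 3202 with weights per array. Of the genes called higher in VAT, 577 were shared by Tregs and Tconvs, where independent lists would share 95.5, and of those called lower 419 against 66.2.

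The effect that the series title names is that of Pparg in VAT Tregs. In mut VAT Tregs, Hpgd, which breaks down prostaglandins, was at least 8.83-fold lower (37.8 ± 5.0 against 809 ± 413, mean ± SD, n = 3 each; log2 -4.30 ± 0.22 SE). Il10 was 14.9-fold lower (182 ± 116 against 2486 ± 1027), Cxcl2 at least 15.9-fold, Ccr1 at least 7.75-fold, Ccr3 9.72-fold, Frmd5 14.2-fold, the protease gene Ctsh at least 6.51-fold, and Plin2, the lipid droplet coat gene, 8.39-fold (357 ± 91.2 against 2972 ± 524). The largest increases were in the transcription factor gene Bhlhe40 (7.09-fold, 2273 ± 104 against 325 ± 61.8, log2 2.83 ± 0.29), Cd96 (5.68-fold), Parp8 (at least 3.66-fold), Ms4a4b (5.67-fold), Gramd3 (5.66-fold), Iigp1 (at least 3.04-fold), St8sia6 (at least 4.01-fold) and Nt5e, which encodes the ectoenzyme CD73 (5.34-fold). Foxp3 was not called (2520 ± 203 against 2595 ± 15.6, log2 -0.05 with a 95% interval of -0.39 to 0.30, adjusted p = 0.993), nor were Il2ra (-0.37 ± 0.18, adjusted p = 0.382), Klrg1 (-1.03 ± 0.33, adjusted p = 0.0727) and the fatty acid transporter gene Cd36 (0.14 ± 0.17, adjusted p = 0.918). Cd36 lay at 27.8 ± 5.9 in mut and 25.2 ± 5.7 in wt, both under 83.8, so its missing call does not show that it was unchanged. The same holds for Klrg1, which stood at 3598 ± 610 in mut against 7261 ± 118 in wt with no overlap between the arrays. Ccr2 fell (-1.93 ± 0.29, adjusted p = 3.58e-05), and so did Gata3 (-0.44 ± 0.11, adjusted p = 0.0149), whose call was lost under 3 of the alternatives. limma called 1031 genes, 445 higher and 586 lower in mut, and 250 of at least 2-fold. The count was 672 without mut array 2, 675 without wt array 2, 2457 with weights per array and 1548 with only these 6 arrays in the fit.

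VAT Treg markers fell in 12 of 19 cases (13 adjusted over the list alone) and Tnfrsf9 rose (median -0.84, camera adjusted p = 1.65e-17, and adjusted p = 0.0456 with an estimated correlation). Cytokine genes rose in 10 of 19 cases (11 adjusted over the list alone) and Il10 fell (median 0.49, adjusted p = 4.37e-11, and adjusted p = 0.0054 with an estimated correlation), among them Csf2 (at least 2.09-fold), the type 2 cytokine gene Il13 (2.56-fold, 386 ± 57.0 against 150 ± 8.6) and Lta (at least 1.46-fold). The remaining list calls did not hold with an estimated correlation. Naive and lymphoid-homing genes rose in 8 of 16 (9 adjusted over the list alone), such as Satb1 (1.93), Ccr7 (1.92) and Bach2 (1.79), with Klf2 lower (adjusted p = 0.106 with an estimated correlation). Sterol synthesis genes fell in 6 of 15 (12 adjusted over the list alone; median -0.42, adjusted p = 0.106 with an estimated correlation), including Nsdhl (-0.97), Hmgcs1 (-0.79) and Sqle (-0.75). Immediate early and stress genes fell in 11 of 24 (14 adjusted over the list alone) and Egr2 rose (median -0.56, adjusted p = 0.11 with an estimated correlation), with Hspa1a, a heat shock gene, at -2.72 and Dnajb1 at -1.25. Treg identity genes rose in 9 of 24 (11 adjusted over the list alone), Lrrc32 at 2.38, Itgae at 2.15 and Cd83 at 2.00, and Capg and Swap70 fell (adjusted p = 0.11 with an estimated correlation). Fatty acid oxidation genes fell in 3 of 19 (median -0.27, adjusted p = 0.255 with an estimated correlation), and 4 of 20 interferon-stimulated genes (6 adjusted over the list alone) and 4 of 13 NF-kB genes (6 adjusted over the list alone) rose (adjusted p = 0.365 and adjusted p = 0.271 with an estimated correlation). Inhibitory and costimulatory receptor genes rose in 4 of 17 cases (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.000706, and adjusted p = 0.307 with an estimated correlation), namely Btla (1.58 ± 0.15), Cd200 (1.30), Cd28 (0.84) and Tnfrsf9 (0.75). Lineage transcription factors gave 4 higher, with Ahr at 1.36 and Tbx21 at 1.22, and 5 lower of 18 (6 higher adjusted over the list alone; adjusted p = 0.407, with a median of -0.03 but a mean of 0.19). The chemokine receptor and adhesion list split into 6 higher and 10 lower of 24 (adjusted p = 0.0608), Cxcr3 at 1.76 among the former. Lipid uptake and storage genes gave 1 higher and 2 lower of 29 (adjusted p = 0.984) and glycolysis genes 1 higher, Hk2, of 15 (adjusted p = 0.701). No cell cycle gene passed in limma, although the list's median of 0.36 did with the preset correlation (adjusted p = 1.12e-05, and adjusted p = 0.498 with an estimated correlation).

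**Figure D2:**
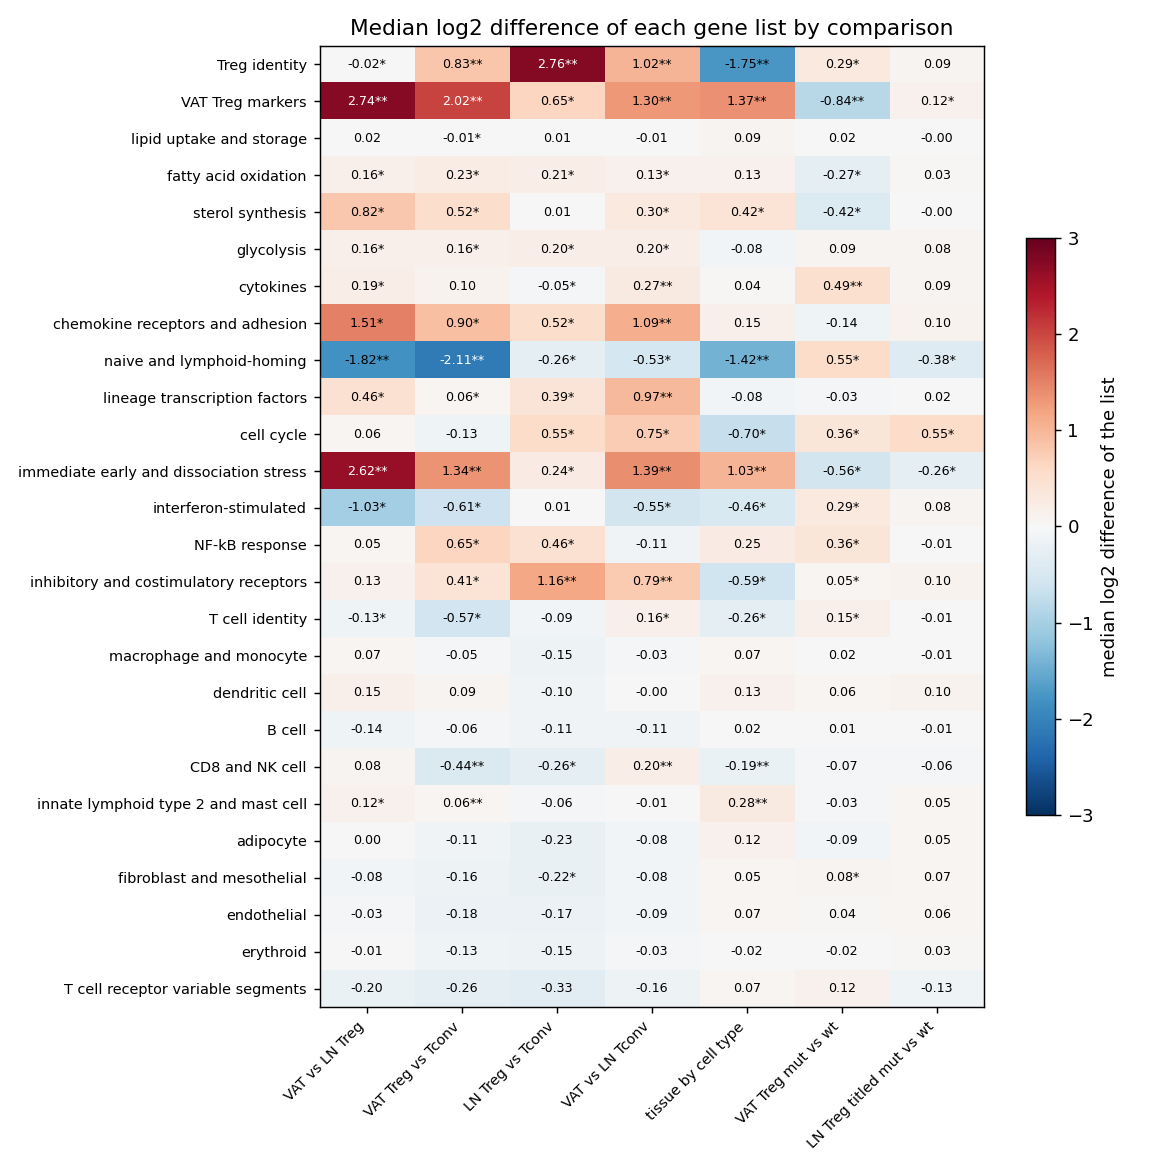
Median log2 difference of the measured genes of each of the 26 lists (vertical axis) in 7 of the comparisons (horizontal axis), coloured from lower to higher with the colour limited at 3 either way; 1 star marks a camera adjusted p under 0.05 and 2 stars a call that held with an estimated correlation too. VAT Treg markers had medians of 2.74 in VAT against LN Tregs and -0.84 in mut against wt VAT Tregs.

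A further question was whether the genes that set VAT Tregs apart moved with Pparg. The VAT Treg signature comprised the 663 genes higher and 327 genes lower by at least 2-fold in VAT than in LN Tregs of retired breeders, which are other arrays than those of the Pparg lines. Of the 663 higher genes, 320 fell, 10 rose and 333 did not pass in mut against wt VAT Tregs, with a median log2 difference of -0.51, and 86.4% lay below 0. Of the 327 lower genes, 182 rose, 0 fell and 145 did not pass, with a median of 0.58, and 94.2% lay above 0. Both shifts passed in camera (p = 6.01e-73 and 3.53e-107), with an estimated correlation (p = 0.000214 and 2.24e-05) and in fry (p = 1.23e-06 and 5.06e-08). Across all tested genes, which are not independent replicates, the log2 differences of both comparisons correlated at a Pearson's r of -0.606. Of all calls, 507 genes were higher in VAT and lower in mut, against 62.4 for independent lists, and 292 were lower in VAT and higher in mut, against 49.7.

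**Figure D3:**
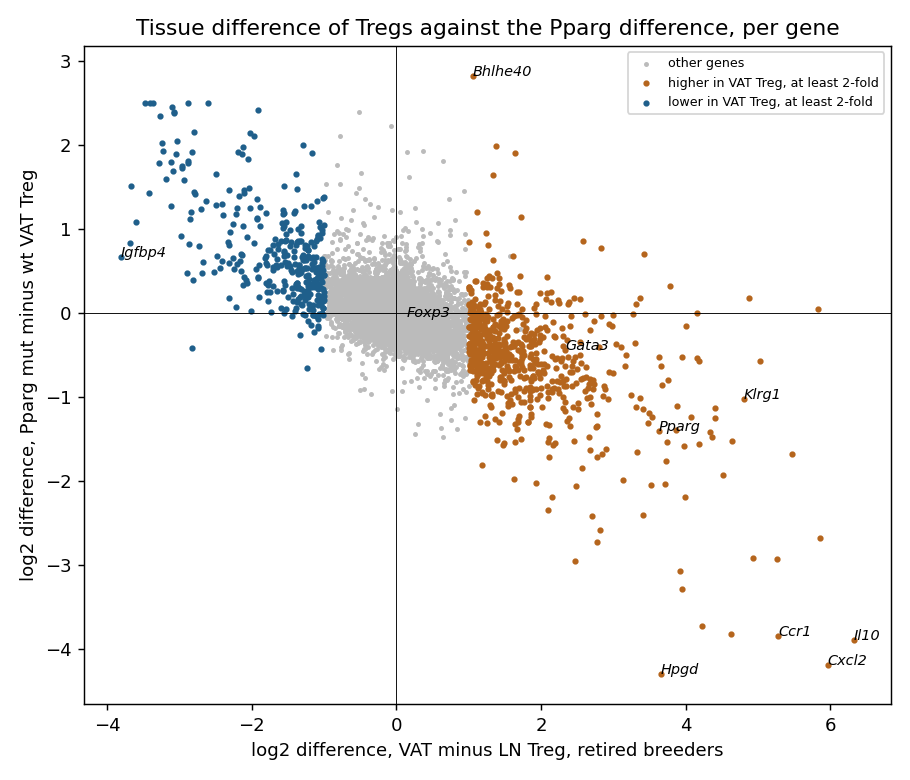
Log2 difference between VAT and LN Tregs of retired breeders (horizontal axis) against the log2 difference between mut and wt VAT Tregs (vertical axis), 1 point per tested gene, with the VAT Treg signature in colour and the other genes in grey. The 663 genes higher in VAT had a median of -0.51 on the vertical axis and the 327 lower ones a median of 0.58.

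In lymph nodes, the same Pparg comparison gave few calls. By title, 17 of 31 called genes were higher and 14 lower in titled mut LN Tregs, 17 of the 31 by at least 2-fold, with 1013 genes at an unadjusted p under 0.05. The immediate early genes Fos (4.58-fold, 107 ± 12.8 against 494 ± 107, n = 3 each, log2 -2.19 ± 0.27) and Jun (3.93-fold) were lower, together with Hspa1a (-1.82), Cpm (-1.50), Ppp1r15a (-1.38), Ccdc22 (-1.37 ± 0.14, adjusted p = 3.2e-06), Dusp1 (-1.21) and Ncmap (-1.11). Higher were Scp2, a sterol carrier (1.27 ± 0.18), Zc3h12c (1.21, with 0.67 at its other probe set), the interleukin 18 receptor gene Il18r1 (1.21), Sema6d (1.12), the aryl hydrocarbon receptor gene Ahr (1.01), Hrh4 (1.01), Kynu (1.01) and Mid2 (0.95). Both groups lay under 83.8 for Hrh4 (57.1 against 27.7), Kynu (48.6 against 23.5) and Mid2 (78.3 against 40.7), so these genes are not shown to be above background. Leaving out an array or changing a setting ended the calls of Hspa1a in 10, Dusp1 in 7, Hrh4 in 7, Kynu in 3, Ahr in 2 and Mid2 in 2 of the alternatives. The count was 13 without titled mut array 2, 47 without titled mut array 3, 16 and 15 without titled wt arrays 2 and 3, 17 without titled mut array 1, 62 with weights per array and 17 with columns shifted to the same median. Foxp3 did not pass (log2 -0.45 ± 0.17, adjusted p = 0.787), and titled wt array 2 stood at 5159 against 2630 and 3553 in the other arrays of its group.

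Of the 31 genes, 26 had the same sign in VAT by these titles, and 19 were called with the same sign in both tissues, such as Cpm (VAT -2.58), Il18r1 (VAT 2.40), Sema6d (VAT 2.23), Zc3h12c (VAT 1.91, with 1.36 at its other probe set) and Ccdc22 (VAT -1.36 ± 0.14, adjusted p = 5.05e-08). Dag1, Pard6g, Naip5, Hrh4 and Scp2 (VAT -1.20) had opposite signs, and these and the VAT values of Ccdc22 were chosen after they were seen. Of the lists, 4 passed with the preset correlation and 0 with an estimated correlation. They were the immediate early and stress genes (4 of 24 lower, 9 adjusted over the list alone, median -0.26, adjusted p = 0.19 with an estimated correlation) and naive and lymphoid-homing genes (0 of 16 called, 7 lower adjusted over the list alone, median -0.38, adjusted p = 0.19 with an estimated correlation). The others were cell cycle genes (0 of 29, median 0.55, adjusted p = 0.575 with an estimated correlation) and VAT Treg markers (0 of 19, 1 higher adjusted over the list alone, median 0.12, adjusted p = 0.85 with an estimated correlation). Of the VAT Treg signature, 6 of the 663 higher genes were higher and 7 lower in titled mut LN Tregs (median 0.05, camera p = 0.0264, p = 0.568 with an estimated correlation, fry p = 0.527). Of the 327 lower genes 1 was higher and 0 lower (median -0.09, camera p = 1.44e-07, p = 0.18 with an estimated correlation, fry p = 0.275).

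The difference of the Pparg effect between tissues was tested as an interaction, VAT minus LN by title, which called 500 genes, 236 higher and 264 lower. The mut to wt difference was more negative in VAT for Cxcl2 (log2 -4.29 ± 0.30), Hpgd (-4.21), Il10 (-3.95), Ccr1 (-3.79), Ctsh (-3.78) and Pparg (-1.47 ± 0.19, adjusted p = 8.29e-06), and more positive for St8sia6 (2.69), Parp8 (2.61), Satb1 (2.60), Ms4a4b (2.60) and Lrrc32 (2.59). VAT Treg markers were more negative in 8 of 19 cases (15 adjusted over the list alone), cytokine genes more positive in 6 of 19 (9 adjusted over the list alone) with Il10 the exception, and naive and lymphoid-homing genes more positive in 8 of 16 (13 adjusted over the list alone). These 3 lists held with an estimated correlation (adjusted p = 0.022 for each). With the LN sign turned, as the genotype fields would have it, 577 genes were called, and 1088 with weights per array.

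Within the Pparg lines, VAT and LN Tregs were also compared for each title. In wt mice 3751 genes were called, 1700 higher and 2051 lower in VAT. Anxa1 (at least 34.8-fold), Lilr4b (at least 29.0-fold), Cxcl2 (at least 15.9-fold), Pcsk1 (at least 28.7-fold) and Il10 (at least 28.1-fold) led the increases, and Iigp1 (-3.84), St8sia6 (-3.75), Satb1 (-3.66), Igfbp4 (-3.66) and the peptidase gene Dpp4 (-3.61) the decreases. Pparg was at least 6.32-fold higher in wt VAT Tregs (log2 3.09 ± 0.13), Klrg1 23.4-fold, Gata3 4.10-fold and Ccr2 14.4-fold. Foxp3 was called lower in wt VAT than in titled wt LN Tregs (2595 ± 15.6 against 3781 ± 1280, log2 -0.49 ± 0.17, adjusted p = 0.043), a call lost under 8 of the alternatives, among them the other LN group (-0.04, adjusted p = 0.94). In mut mice 1972 genes were called, 817 higher and 1155 lower. Lilr4b (at least 29.4-fold), Rgs2 (26.6-fold), Lilrb4a (23.4-fold), Fos (23.1-fold) and Fosb (22.1-fold) led, with Igfbp4 (-2.80), Tlr7 (-2.66), Gcnt1 (-2.27), Nsg2 (-2.23) and Ctsw (-2.05) lowest. Il10 was at least 1.89-fold higher in mut VAT than in titled mut LN Tregs (182 ± 116 against 59.9 ± 9.9, n = 3 each, log2 1.42 ± 0.31), Klrg1 10.4-fold and Gata3 2.93-fold. Of the 663 higher signature genes 620 were higher in wt and 417 in mut VAT Tregs than in LN Tregs (medians 1.23 and 0.67). Of the 327 lower genes, 320 and 248 were lower (medians -1.42 and -0.72), and 2 went the other way in mut. Immediate early and stress genes were higher in 21 of 24 cases in wt (22 adjusted over the list alone) and in 20 of 24 in mut (21 adjusted over the list alone), with adjusted p = 0.00317 and adjusted p = 0.000337 with an estimated correlation. Cytokine genes were higher in 9 of 19 cases in mut (11 adjusted over the list alone; adjusted p = 0.00175 with an estimated correlation), where Il5 rose at least 2.56-fold and Csf2 at least 2.09-fold. These tissue comparisons use LN groups whose titles and genotype fields contradict each other, and against the other LN group of the Pparg lines 3331 and 2672 genes were called. The same sign in VAT of 26 of the 31 LN calls by title argues against crossed titles without settling the labels. The mut count was 3161 with weights per array.

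Markers of other cells that a sort could hold were measured alongside. Between VAT and LN Tregs of retired breeders, 3 of 18 macrophage and monocyte genes were higher (0 adjusted over the list alone; list adjusted p = 0.281). So were 2 of 14 dendritic cell genes (adjusted p = 0.39), among them H2-Eb1 at 279 ± 144 against 110 ± 11.6. None, 0 of 15, of the fibroblast and mesothelial genes passed in limma (median -0.08, adjusted p = 0.95). B cell genes gave 3 of 14 lower (adjusted p = 0.216) and CD8 and NK cell genes 2 higher and 1 lower of 15 (adjusted p = 0.584). Adipocyte genes gave 1 higher, Fabp4, and 1 lower, Lipe, of 13 (adjusted p = 0.875), and endothelial genes 1 lower, Pecam1, of 12 (adjusted p = 0.31). Erythroid genes gave 0 of 4 (median -0.01, adjusted p = 0.875) and T cell receptor variable segments 1 lower of 7 (adjusted p = 0.683, with a median of -0.20 but a mean of 0.02). T cell identity genes gave 3 of 13 lower (adjusted p = 0.0431, and adjusted p = 0.603 with an estimated correlation). Innate lymphoid type 2 and mast cell genes were higher in 6 of 13 cases, such as Kit (2.71-fold), and Il17rb was lower (adjusted p = 0.000846, and adjusted p = 0.0548 with an estimated correlation). That list shares Gata3, Rora, Il5 and Il13 with the other lists. VAT Treg array 3 of retired breeders stood apart in Cd74, an antigen presentation gene (601 against 124 and 90), and in Lyz2, a myeloid gene (232 against 38 and 39), both chosen after their values were seen. Between mut and wt VAT Tregs, 1 of 18 macrophage and monocyte genes was higher, Cybb (0.97 ± 0.25, adjusted p = 0.016), which lost its call under 6 of the alternatives. Cd74 did not pass there (637 ± 37.2 against 308 ± 115, adjusted p = 0.391), and 0 of 13 adipocyte genes passed in limma (median -0.09). Dcn was the 1 of 15 fibroblast and mesothelial genes that was higher (0.83 ± 0.19; list adjusted p = 0.024, and adjusted p = 0.488 with an estimated correlation). Of the list of innate lymphoid type 2 and mast cells, 3 of 13 genes were higher, such as Il17rb (at least 3.82-fold), with Gata3 lower (adjusted p = 0.0728, with a median of -0.03 but a mean of 0.28). Endothelial genes gave 1 higher of 12, Pecam1 (0.97 ± 0.13, adjusted p = 8.77e-06; list adjusted p = 0.223), and CD8 and NK cell genes 1 lower of 15, Itga2 (-0.95 ± 0.20, adjusted p = 0.00267; list adjusted p = 0.419), whose call was lost without mut array 2. T cell identity genes were higher in 2 of 13 cases, Cd28 and Trat1 (1.44 ± 0.17) (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.000618, and adjusted p = 0.271 with an estimated correlation). Of 7 T cell receptor variable segments 1 was higher, Trav7n-5 (177 ± 25.8 in mut and 66.1 ± 24.5 in wt VAT Tregs, 164 ± 27.3 in titled mut and 180 ± 27.3 in titled wt LN Tregs; log2 1.47 ± 0.25, list adjusted p = 0.286). Of 14 dendritic cell, 14 B cell and 4 erythroid genes 0 passed in limma (list adjusted p = 0.291, 0.623 and 0.984). The call of Dcn, too, was lost under 2 of the alternatives, without mut array 3 and without wt array 2.

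The other tissue comparisons held marker calls as well. Between VAT and LN Tconvs, 2 of 18 macrophage and monocyte genes were higher (3 adjusted over the list alone; list adjusted p = 0.255, with a median of -0.03 but a mean of 0.16). They were Cybb (265 ± 77.6 against 53.7 ± 8.6, log2 2.27 ± 0.25, adjusted p = 2.96e-07) and Ctsd (0.66 ± 0.18, adjusted p = 0.0172), whose call was lost under 5 of the alternatives. Pecam1 was the 1 of 12 endothelial genes that was lower (-0.49, lost under 6 of the alternatives; list adjusted p = 0.423). Dendritic cell, B cell, adipocyte, fibroblast and mesothelial, and erythroid genes gave 0 calls in limma there (list adjusted p = 0.774, 0.493, 0.582, 0.631 and 0.829). Between wt VAT and titled wt LN Tregs, 2 of 14 dendritic cell genes were higher (list adjusted p = 0.204). They were H2-Eb1 (250 ± 50.6 against 126 ± 18.8, log2 0.98 ± 0.26, adjusted p = 0.00635) and H2-Ab1 (203 ± 141 against 57.4 ± 3.6, log2 1.62 ± 0.55, adjusted p = 0.0387), whose call was lost under 9 of the alternatives. Fabp4 was higher (0.65 ± 0.15, adjusted p = 0.00202, lost with the other LN group) and Lipe lower (-0.52) among 13 adipocyte genes (list adjusted p = 0.457). Fn1 was the 1 of 15 fibroblast and mesothelial genes that was higher (0.64 ± 0.16, adjusted p = 0.00335; list adjusted p = 0.204). Of 14 B cell genes 3 were lower (adjusted p = 0.317), and 0 of 18 macrophage and monocyte genes passed in limma (adjusted p = 0.428). Between mut VAT and titled mut LN Tregs, 2 of 15 fibroblast and mesothelial genes were higher, Fn1 (0.99 ± 0.16, adjusted p = 5.96e-05) and Dcn (0.71 ± 0.19, adjusted p = 0.0127, lost under 3 of the alternatives). That list had adjusted p = 0.0199, and adjusted p = 0.45 with an estimated correlation. Macrophage and monocyte genes (median 0.16, adjusted p = 0.0199, and adjusted p = 0.399 with an estimated correlation) gave 0 of 18 calls in limma. Dendritic cell genes (median 0.16, adjusted p = 0.0251, and adjusted p = 0.462 with an estimated correlation) gave 0 of 14. Pecam1 was lower in both YFP+ comparisons (-2.35 in wt and -0.98 in mut). Both groups lay below the lowest array median for Fn1 and Fabp4.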

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

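The splits of the arrays were planned before the results were seen, and all other tests of explanations in this part were chosen only after seeing the result they address. Outliers were not tested in groups of 3.

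A difference between groups led to the first results given here. The VAT to LN difference was not the same in Tregs and Tconvs of retired breeders for 1503 genes, by a test of the interaction. The largest positive interactions on the log2 scale, Tregs minus Tconvs, were Cxcl2 6.17, Pcsk1 5.26, Ccr1 5.17, Kcna4 5.06 and Frmd5 4.74. The largest negative ones were Cxcr3 -4.34, Ctsw -4.25, Cxcr5 -4.21, Ifng -4.17 and Slamf6 -3.90. The sign does not say which cell type differed between tissues: Ctsw was lower in VAT than in LN Tregs by a log2 of -3.67. The effect of the Pparg genotype likewise differed between VAT and LN, by title, for 500 genes. The largest were St8sia6 2.69, Parp8 2.61, Satb1 2.60, Ms4a4b 2.60 and Lrrc32 2.59, and Cxcl2 -4.29, Hpgd -4.21, Il10 -3.95, Ccr1 -3.79 and Ctsh -3.78.

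A signal in data the comparisons did not use led to the next values: of the 4013 probe sets with several gene symbols or none, many passed the same test. The calls numbered 782 for VAT against LN Tregs, 657 for VAT Tregs against VAT Tconvs, 252 for LN Tregs against LN Tconvs, 221 for VAT against LN Tconvs and 179 for their interaction. They numbered 94 for mut against wt VAT Tregs, 11 for the same in LN by title, 54 for that interaction, and 682 and 301 for VAT against LN Tregs of the wt and mut mice. What these probe sets measure was not settled, and no explanation was tested.

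The first pattern weighed is the rise of immediate early and stress genes in VAT Tregs. Had the preparation of fat acted alike on both cell types, the interaction of the list would lie near 0. Its median was 1.03 (camera p = 0.00387 with an estimated correlation), which argues against an equal action as the whole cause. A stronger response of Tregs to the same preparation would give such an interaction too, so preparation is not excluded for the excess in Tregs. The median of 1.39 in VAT against LN Tconvs is the part that both cell types shared, and for it preparation and biology cannot be told apart, since all VAT cells came from fat and all LN cells from nodes.

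The second pattern is the set of genes that differed between titled mut and titled wt in LN and in VAT alike. If the LN titles were crossed between genotypes, shared genes would have opposite signs, yet 26 of 31 had the same sign (exact 95% interval 66.3% to 94.5%), which argues against crossed titles. The interval takes the genes as independent, but they come from the same arrays, so it does not measure the spread between pools. Less handling stress in the mut preparations stays open: of the 19 genes called alike in both tissues 3 are in the stress list and 16 outside it, but that list holds only 24 measured genes and others can respond to stress. A difference near the Foxp3 gene between the mouse lines stays open too: Ccdc22, a neighbour of Foxp3, was at -1.36 in VAT and -1.37 in LN. For this gene, a line difference and an effect of Pparg cannot be told apart.

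The third pattern is the fall of the VAT Treg signature in mut VAT Tregs. A fixed share of LN-type Tregs in the mut sorts would lower every higher-set gene in proportion, but 190 of the 620 such genes also called higher in wt VAT than LN Tregs differed from the fall that the median implied share of 55.8% predicts (LN profile: mean of both LN groups of the Pparg lines), which argues against 1 fixed share. Fewer Tregs in the mut sorts is argued against as the whole cause by Foxp3, whose lower 95% bound of -0.39 lies above the median fall of -0.51. The bound is that of 1 gene, the median was given no error, and a smaller loss of Tregs is not excluded. The fall was not limited to genes called between VAT and LN Tconvs: the 349 signature genes not called there had a median of -0.58 (camera p = 1.71e-06 with an estimated correlation). A missing call in Tconvs does not show that a gene is free of a response to preparation, so a weaker response of this kind is not excluded. A biological effect of Pparg on these genes, in the cells or on which cells were present, stays open.

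With 10 splits of 6 arrays, the share of splits that reach the real value is never under 0.05. Every other split mixes the real groups, so a real difference enters the spread within groups and lowers the calls. A low count in the other splits therefore does not measure what chance alone would give. For called genes, 1 of the 10, the real split, reached the real count for VAT against LN Tregs (4263, highest other 0), VAT Tregs against VAT Tconvs (3376, highest other 0), LN Tregs against LN Tconvs (1786, highest other 239), VAT against LN Tconvs (1489, highest other 14), mut against wt VAT Tregs (1031, highest other 0) and VAT against LN Tregs in wt (3751, highest other 0) and mut (1972, highest other 0). For LN Tregs by title 2 of the 10 reached 31, the other with 172 calls; it set titled mut arrays 1 and 2 with titled wt array 1 against the rest, a structure of the samples other than the titles. The signature medians in VAT, 0.51 and 0.58 in size, were reached by 1 split each (highest other 0.29 and 0.31). In LN, 0.05 was reached by 1 (highest other 0.04) and 0.09 by 4 (highest other 0.16). For the interactions 7 of 100 splits reached 1503 calls (highest 4944) and 5 of 100 reached 500 (highest 2264); these splits mix tissues and cell types or genotypes, so the large differences between groups enter their contrast.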

How the results depend on the processing

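Most alternatives were planned; those said to be added were chosen after seeing the data. Of 650 calls of named genes with 11555 alternative values, 11046 kept direction and call, 509 kept the direction without the call (324 of them with an array left out) and 0 reversed. That tally leaves out the genotype field for the LN comparison by title, since this setting turns all signs there by definition. With weights per array, calls numbered 7963 for VAT against LN Tregs, 8364 for LN Tregs against LN Tconvs (36.5% of them higher in Tregs), 2795 for VAT against LN Tconvs and 3202 for the interaction of tissue and cell type. They numbered 2457 for mut against wt VAT Tregs, 62 for the same in LN by title, 1088 for that interaction and 3161 for VAT against LN Tregs in mut. With a limit of 2-fold beside the adjusted p, and so fewer genes by construction, calls in the order of the report were 990, 823, 334, 314, 736, 250, 17, 263, 798 and 342. By 2-fold alone they were 992, 825, 339, 319, 773, 252, 21, 294, 802 and 346. With only the compared groups in the fit, calls were 1146 for LN Tregs against LN Tconvs, 948 for VAT against LN Tconvs and 1548 for mut against wt VAT Tregs. Columns shifted to the same median left 17 calls in LN by title. Added later, omission of replicate 3 of all 4 groups of retired breeders left 960 for LN Tregs against LN Tconvs and 789 for VAT against LN Tconvs. Other than by the fewer arrays or genes used, the cause was not tested. With the LN genotype taken from its field, the LN calls were 31 with signs turned and the interaction 577.

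The signature in VAT kept direction and call throughout, also, added later, without the stress list (-0.50 and 0.58) and without genes called in VAT against LN Tconvs (-0.58 and 0.66). In LN by title, the higher set lost its call with weights per array (median 0.05, p = 0.494), the offset of 50 (0.03, p = 0.125), the dimmest 40% of genes left out (0.05, p = 0.0583), an estimated correlation (0.05, p = 0.568) and the signature by adjusted p alone (0.03, p = 0.229). The lower set lost it with an estimated correlation (-0.09, p = 0.18) and by adjusted p alone (-0.01, p = 0.0626). An estimated correlation in place of the preset changed the number of lists called, in the order of the report, from 13 to 3, 16 to 6, 14 to 2, 15 to 8, 11 to 6, 13 to 2, 4 to 0, 11 to 3, 13 to 3 and 15 to 5.

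With 1 array left out, calls ranged from 3562 to 4062 for VAT against LN Tregs, 2430 to 3326 for VAT Tregs against VAT Tconvs and 983 to 4178 for LN Tregs against LN Tconvs (983 without LN Treg array 3, 1088 without LN Tconv array 2, 1174 without LN Treg array 2, 4178 without LN Treg array 1). They ranged from 828 (without VAT Tconv array 3) to 1906 for VAT against LN Tconvs, and 1302 to 1565 for their interaction. They ranged from 672 (without mut array 2; 675 without wt array 2) to 1009 for mut against wt VAT Tregs and from 13 to 47 in LN by title, where the omission of titled mut arrays 1, 2 or 3 or titled wt arrays 2 or 3 moved the count by over 1.5 times. They ranged from 344 to 546 for that interaction, 2974 to 3584 for VAT against LN Tregs in wt and 1428 to 1763 in mut. The signature medians ranged from -0.56 to -0.46 and 0.54 to 0.64 in VAT and from 0.04 to 0.07 and -0.17 to -0.02 in LN, where the higher set lost its call without titled wt array 1 or 2 or titled mut array 2 or 3 and the lower set without titled mut array 1.

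The replicate block gave 4418, 3618, 2127, 1603, 1589, 1116, 36, 549, 3936 and 2118 calls in the order of the report, and signature medians of -0.51 and 0.58 in VAT and 0.05 and -0.09 in LN. Arrays of the same number did not pair by the rule set beforehand: in no comparison did all pairs correlate above 0.1, although all 6 arrays did best with their own number for VAT against LN Tconvs and for VAT against LN Tregs in mut, a hint from the data and not the design.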

Other observations

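Both tests in this part were chosen only after seeing the results they address.

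In wt and mut VAT Tregs alike the type 2 cytokine gene Il5 was above its level in LN Tregs of the same title (log2 1.57 ± 0.16 SE in wt and 2.74 ± 0.16 in mut, n = 3 each). Over the VAT groups its mean was lowest in Tconvs of retired breeders (37.9 ± 0.6). Pparg stood at 532 ± 68.2 in wt, 199 ± 2.2 in mut and 83.4 ± 5.0 in Tconvs. The mean log2 level of the Treg identity list was 9.56 in wt and 10.08 in mut VAT Tregs, 9.58 in VAT and 10.08 in LN Tregs of retired breeders, and 8.44 and 7.12 in VAT and LN Tconvs.

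The rise of cytokine genes in mut VAT Tregs was set against the presence of Tconvs in the mut sorts. Of the 10 cytokine genes called higher in mut, only 4 (Ifng, Il4, Il2 and Lta) were called higher in VAT Tconvs than in VAT Tregs, which argues against Tconvs as the whole cause.

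A further question was whether signature genes that were not called between VAT and LN Tconvs moved more with Pparg than those that were. The 349 higher-set genes not called between VAT and LN Tconvs had a median of -0.58 in mut against wt VAT Tregs and the 314 called in that Tconv comparison (310 higher and 4 lower in VAT) a median of -0.43, a difference of -0.15 (p = 0.0002 by permutation of genes, which are not independent of each other). The split does not separate genes of Tregs from genes of Tconvs, since 608 of the 663 genes were called higher in VAT Tregs than in VAT Tconvs. The same arrays gave both medians, so the difference was not tested on other data.

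Among the neighbours of Foxp3 other than Ccdc22, 2010204K13Rik was lower in mut than in wt VAT Tregs (-0.37, adjusted p = 0.0457) and no other passed. By array, Ccdc22 stood at 184, 190 and 194 in mut and 452, 501 and 510 in wt VAT Tregs, and at 149, 194 and 177 in titled mut and 387, 551 and 415 in titled wt LN Tregs. For 4 of the 24 arrays the closest array by correlation was in another group, all of them LN Tregs. Titled wt arrays 2 and 3 were closest to titled mut array 3 (r = 0.9913 and 0.995), titled mut array 3 to titled wt array 3 (0.995), and array 1 of retired breeders to titled wt array 1 (0.9921).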
